A study of Homo sapiens with 117 samples.

How the data were processed

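Total RNA of PBMC from participants with GWI and from HC was measured at T0 before exercise, T1 at VO2max and T2 4 hours after T1, with 20, 18 and 20 libraries in GWI and 19, 20 and 20 in HC. Per the labels, RNA was extracted with RNAzol, had an RNA integrity number above 7, and was made into libraries with a stranded total RNA kit. The processing notes of the series name build GRCh38, GSNAP, HISAT2, STAR, HTSeq and DESeq2, with no versions, no stated role for each tool and no strand setting. The deposited files of the 117 libraries hold raw counts of reads per gene, as whole numbers for 58051 gene identifiers followed by the 5 special rows that HTSeq writes, which were kept out of the library sizes. A deposited table of the series holds counts of 15620 genes, and 115 of its 117 columns equal the file of their own library. The other 2, GWI T0 replicates 1 and 4, hold each other's values, and each replicate was taken from its own file. A second deposited table, with counts divided by 1 factor per library, was not used.

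Of the gene identifiers, 57447 were found in GENCODE release 29 (GRCh38), from which gene names, positions and overlaps were taken, and 517 genes, those of chromosome Y with XIST and TSIX, were left out. Over the 117 libraries the median share of reads inside genes was 32.6% (19.3 to 45.9%), outside any gene 42.1% (25.5 to 56.3%), not aligned 7.87%, not unique 5.77%, ambiguous between genes 4.94% and of low quality 4.06%. Reads that fit several genes are absent from the counts, which lowers the level of genes with near copies.

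Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, over the 6 groups), which left 20607. Each comparison used the libraries of its own groups, TMM normalization and the quasi-likelihood F test of edgeR (robust dispersion estimates), with a gene called at a Benjamini-Hochberg adjusted p under 0.05. There were 12 comparisons: GWI against HC at each of the 3 times, the 3 pairs of times within each condition, and 3 interactions of condition with time. Libraries of a participant were treated as independent in the main test because the labels do not give the pairing. Log2 CPM values used a prior count of 2, and R 4.3.3, limma 3.58.1, DESeq2 1.42.0, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

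The tests were run on 29 gene lists written by hand, of blood cell types and of stress, hormone, immune and metabolic responses. Each list was tested with camera of limma at its preset correlation between genes of 0.01 and, as an alternative, with the correlation estimated from the data, adjusted over the 29 lists of a comparison. Counts of called members were given over all genes and also adjusted over the list alone. Named genes followed a rule written before the data were examined: among protein-coding genes that were called, had a mean of at least 5 CPM and were neither sex-linked nor immunoglobulin or T cell receptor segments, the 12 highest and 12 lowest log2 fold changes. Where fewer than 10 genes passed, all that passed and the 5 of smallest p were named, and up to 3 members of smallest p were named for each described list. The 4 gene families described among the other observations were chosen after their values were seen.

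Participants were inferred from numbers in the names of the deposited files, which gave 47 participants, of whom 38 had libraries at 2 or 3 times. This pairing was checked with the correlation of the 1000 genes that vary most after removal of group means. The 102 inferred pairs had a median r of 0.696 (lowest 0.250, highest 0.894). For 5600 pairs of other libraries the median was -0.0227 and the highest 0.899. Of 108 libraries with a partner 100 were closest to one of their own participant, so the pairing is not certain for every library. Pairs that share the number in the sample title, within a condition, had a median r of 0.290.

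The alternatives fixed before the data were examined were RLE normalization, no filter on low counts, the DESeq2 Wald test, the title number as a block, the inferred participant as a block, depth and the share of reads outside genes as covariates, the series of library numbers as a covariate, the genes of the series table alone, the estimated correlation for lists, and the mean log2 CPM of 5 cell type lists as covariates (NK cells, classical monocytes, B cells, naive and central memory T cells, and platelets). After the data were seen, further alternatives were added: leaving out the 6 libraries with more than 30 CPM of 12 brain marker genes, with and without the participant block, an offset per library for GC content in 25 bins, leaving out each library in turn, and permutation of list means with 100000 resamples. Each comparison was also repeated on 100 splits of its libraries, the real one included, and the interactions with the participant block on 100 splits of the participants, added after the data were seen. Seeds were 20 in R and 7 for the permutations.

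The tests were tested on simulated data with 50 genes changed at each fold. At a 2-fold change 82% were recovered for GWI against HC at T0, 74% at T1, 96% at T2, 74% for T1 against T0 in GWI, 86% for T2 against T0 in HC and 48% for the interaction of T2 against T0. False calls made up 5.80 to 14.6% of the calls, above the 5% sought in each case. The 14.6% was that of T2 against T0 in HC with the participant block. Each gene was simulated independently of the others, so these shares leave out structure that real libraries share across genes. At a 1.25-fold change recovery was between 0 and 26%, so at the present depth and number of participants small changes are mostly missed.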

Results

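Total RNA of peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes separated from blood, was sequenced from people with Gulf War Illness (GWI), a chronic multisymptom illness of veterans of the Gulf War, and from healthy controls (HC). Blood was taken around an exercise challenge at 3 times, which are T0 before exercise, T1 at VO2max (the peak rate of oxygen uptake) and T2 during recovery, 4 hours after T1. No group went without exercise, so for every gene and list below effects of exercise cannot be told apart from those of the hour of the day. The 117 libraries fell into 6 groups, with 20 GWI libraries at T0, 18 at T1 and 20 at T2, and 19 HC libraries at T0, 20 at T1 and 20 at T2. The reads counted in genes had a median of 17.9 M per library, with a range of 7.85 to 52.5 M. Group medians at T0, T1 and T2 were 18.5, 19.4 and 16.9 M in GWI and 17.7, 18.5 and 16.6 M in HC. Levels are given in CPM, the counts of a gene per M counts in genes, as means ± SD over the libraries of a group, and log2 fold changes carry their standard error (SE). Positions are on build GRCh38, and each gene named with a position is an annotated gene spanning it.

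GWI and HC before exercise were compared to ask whether resting PBMC differ with the illness. Haemoglobin transcripts of red cell precursors averaged lower in GWI. HBB, the beta globin gene, stood at 62 ± 177 CPM in GWI (n = 20) and 336 ± 564 CPM in HC (n = 19). Single libraries weigh on these means, as GWI T0 replicate 12 held 0.093% haemoglobin transcripts against a median of 0.00243% in GWI and 0.00588% in HC. The HC mean rests on a few libraries, with 0.127, 0.112, 0.112 and 0.204% in HC T0 replicates 3, 11, 12 and 15. Without each library in turn the log2 fold change of HBB lay between -3.88 and -1.94, which does not show the weight of several libraries together. All 8 measured members of the erythroid list were lower in GWI, with a median log2 fold change of -1.80. Interferon-stimulated genes, which are induced by antiviral cytokines, leaned the other way, with 24 of 29 members higher in GWI (median 0.21). The viral RNA sensor gene DDX58 averaged 64.8 ± 18 CPM in GWI and 48.2 ± 15.3 CPM in HC, and SAMD9L, an interferon-induced restriction factor, 163 ± 56.5 and 112 ± 44.4 CPM. Among 12 markers of non-classical monocytes, 11 were higher in GWI, including the fractalkine receptor gene CX3CR1 at 229 ± 77.3 against 135 ± 96 CPM. None of these single genes passed the test over all genes (edgeR, Benjamini-Hochberg adjusted p = 0.344 for HBB, 0.336 for DDX58 and SAMD9L, and 0.344 for CX3CR1).

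At T0 edgeR called 0 genes between GWI and HC, 1995 genes had an unadjusted p under 0.05, and DESeq2 called 1 gene, SLCO4A1, lower in GWI. The 5 genes of smallest p were LTF, ADGRG3, PPP1R16B, SLCO4A1 and AC098613.1. LTF encodes lactoferrin of neutrophil granules (ENSG00000012223, chromosome 3, 46435645 to 46485234) and had a log2 fold change of -2.87 (SE 0.608), from 2.04 ± 4.23 CPM in HC to 0.292 ± 0.284 CPM in GWI. SLCO4A1, an organic anion transporter gene (ENSG00000101187, chromosome 20, 62642445 to 62685785), had -1.65 (SE 0.361), with 1.61 ± 0.963 CPM in GWI and 5.08 ± 5.64 CPM in HC. PPP1R16B, which encodes a regulatory subunit of protein phosphatase 1 (ENSG00000101445, chromosome 20, 38805705 to 38923024), had -0.76 (SE 0.166), with 124 ± 26.5 and 209 ± 106 CPM. ADGRG3 had -1.19 (SE 0.256), and the adjusted p of these genes in edgeR was 0.223, while AC098613.1, a noncoding gene, had 1.11 (SE 0.258, adjusted p = 0.314). Camera with its preset correlation called 14 of 29 lists at T0, 0 with an estimated correlation (lowest adjusted p = 0.18) and 0 by permutation. The erythroid list had an adjusted p of 2.7e-05 (0 members called over all genes, 6 lower when adjusted over the list alone; adjusted p = 0.286 with an estimated correlation). The interferon list had 2.42e-05 (0 called, 6 higher when adjusted over the list alone; adjusted p = 0.495 with an estimated correlation), and the non-classical monocyte list 0.0003 (0 called, 1 higher when adjusted over the list alone; adjusted p = 0.462 with an estimated correlation). All 79 measured ribosomal protein genes were lower in GWI by a small amount (median -0.15, camera adjusted p = 1.41e-09; 0 called, also when adjusted over the list alone; adjusted p = 0.709 with an estimated correlation). Leaving out GWI T0 replicate 12 gave 3 called genes in place of 0, and without a filter on low counts edgeR called 666.

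At the peak of exercise the same contrast asks whether the illness alters PBMC transcripts under stress. PPP1R16B stayed lower on average in GWI, with 138 ± 22.5 CPM (n = 18) against 222 ± 102 CPM in HC (n = 20), a log2 fold change of -0.68 (SE 0.148). Of the 16 circadian clock genes, 12 were lower in GWI (median -0.26), among them CRY1 at 35 ± 11 against 49.4 ± 24.5 CPM and PER1 at 149 ± 85.7 against 259 ± 187 CPM. Of 18 classical monocyte markers, 17 were higher in GWI (median 0.34), and the chemokine receptor gene CCR2 averaged 107 ± 58.7 against 55.6 ± 36.8 CPM. No single gene passed in edgeR: the adjusted p was 0.273 for PPP1R16B, 0.442 for CRY1, 0.443 for PER1 and 0.437 for CCR2.

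edgeR called 0 genes at T1, with 1988 at an unadjusted p under 0.05, and DESeq2 called 2 higher and 9 lower in GWI. Other genes of smallest p were the noncoding AC094085.1 (0.84, adjusted p = 0.273), ALPK1, a kinase gene of innate sensing (0.45, SE 0.103, adjusted p = 0.295 in edgeR) and IGHE, the constant region of immunoglobulin E (-1.72, SE 0.409, adjusted p = 0.295). Camera called 13 of 29 lists at T1, 0 with an estimated correlation (lowest adjusted p = 0.261) and 0 by permutation. The circadian list had an adjusted p of 3.52e-05 (0 genes called, 7 lower when adjusted over the list alone; adjusted p = 0.261 with an estimated correlation). The classical monocyte list had 3.79e-05 (0 called, 3 higher when adjusted over the list alone; adjusted p = 0.593 with an estimated correlation). Leaving out HC T1 replicate 3 gave 1 called gene, and leaving out HC T1 replicate 14 gave 3.

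During recovery, the comparison of GWI with HC asks whether the illness alters the state 4 hours after the peak. A single gene was lower in GWI than in HC. MIR3143, a microRNA gene (ENSG00000265565, chromosome 6, 27147626 to 27147688), stood at 0.111 ± 0.133 CPM in GWI (n = 20) and 0.972 ± 1.17 CPM in HC (n = 20), a log2 fold change of -3.14 (SE 0.474, edgeR adjusted p = 0.000117). This gene lies inside the histone gene cluster, beside HIST1H2AH (chromosome 6, 27147129 to 27147515), so reads of a histone transcript that runs past its end would be counted in it. All 18 measured replication-dependent histone genes, which encode the histones made for DNA replication, were also lower in GWI (median -0.29), for instance HIST1H2BD at 59.4 ± 22.8 against 91.2 ± 51 CPM (edgeR adjusted p = 0.397). All 12 non-classical monocyte markers were higher in GWI (median 0.33), and so were all 9 MHC class II genes, which present antigen (median 0.14). The interferon-stimulated genes had 26 of 29 members higher, with a median of 0.18.

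At T2 edgeR called 0 higher and 1 lower gene, with 1233 at an unadjusted p under 0.05, and DESeq2 called 0 higher and 1 lower. After MIR3143 the smallest p belonged to AL031777.3, a noncoding gene over HIST1H2AD and HIST1H3D (-2.04), PFKFB2 (0.37), PGBD5 (2.72) and AC159540.2 (-0.96), all with an edgeR adjusted p of 0.206. Camera called 9 of 29 lists, 0 with an estimated correlation (lowest adjusted p = 0.329) and 0 by permutation. The histone list had an adjusted p of 1.25e-09 (0 called, 2 lower when adjusted over the list alone; adjusted p = 0.404 with an estimated correlation). The MHC class II list had 6.12e-05 (0 called, also when adjusted over the list alone; adjusted p = 0.329 with an estimated correlation). The non-classical monocyte list had 4.21e-07 (0 called, 1 higher when adjusted over the list alone; adjusted p = 0.329 with an estimated correlation), and the interferon list 4.82e-05 (0 called, also when adjusted over the list alone; adjusted p = 0.831 with an estimated correlation). MIR3143 was called with any single library left out (highest adjusted p = 0.000604). Leaving out HC T2 replicate 12 raised the count to 48, of which 45 were higher in GWI. That library held 150 CPM of summed brain marker genes, while GWI T2 replicate 2, which stayed in, held 3642 CPM. With every library above 30 CPM of these markers left out, 1 gene was called. The count of 48 thus depended on which of these libraries were kept.

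The change from rest to the peak of exercise in HC asks what maximal effort does to circulating cells without the illness. Transcripts of natural killer (NK) cells rose about 2-fold: 21 of the 22 measured NK markers passed, 22 when adjusted over the list alone, with a median log2 fold change of 1.01. GZMB, the gene of the cytotoxic protease granzyme B (ENSG00000100453, chromosome 14, 24630954 to 24634267), rose from 85.1 ± 34 CPM at T0 (n = 19) to 192 ± 65.9 CPM at T1 (n = 20), a log2 fold change of 1.18 (SE 0.171, edgeR adjusted p = 0.000454). It was higher in 15 of 16 participants with both times. PRF1, which encodes the pore-forming protein perforin (ENSG00000180644, chromosome 10, 70597348 to 70602775), rose from 454 ± 202 to 972 ± 329 CPM, and S1PR5, a sphingosine-1-phosphate receptor gene of NK cells, from 49.8 ± 20.1 to 106 ± 35.1 CPM. EOMES, a transcription factor gene of cytotoxic lymphocytes, rose from 25.5 ± 13.7 to 47.8 ± 22.9 CPM, the only member of the 12 CD8 T cell genes to pass (4 when adjusted over the list alone). RHOC rose from 27.8 ± 6.67 to 40.5 ± 11.9 CPM as the only one of the 12 non-classical monocyte markers to pass (3 when adjusted over the list alone).

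In HC between T1 and T0, edgeR called 195 genes that rose and 4 that fell (DESeq2 263 and 10). The 12 highest were ADAMTS1, GZMB, PDGFRB, DTHD1, AKR1C3, KLRF1, PTGDR, ENPP5, CXCR1, FEZ1, NMUR1 and GZMA, with log2 fold changes between 1.33 for the metalloprotease gene ADAMTS1 (SE 0.272) and 1.11 for GZMA (SE 0.193). KLRF1, the gene of an activating NK receptor, rose from 49.5 ± 31.4 to 110 ± 53.9 CPM, and GZMA, the gene of granzyme A, from 66.9 ± 27.2 to 144 ± 67 CPM. PTGDR, a prostaglandin D2 receptor gene, passed with an adjusted p of 0.026 that became 0.0588 without HC T1 replicate 19. The 2 genes that fell and met the naming rule were SLC25A37, a mitochondrial iron carrier gene (-0.46, SE 0.119, edgeR adjusted p = 0.045, which became 0.095 without HC T0 replicate 15) and SERINC5 (-0.42, SE 0.105, adjusted p = 0.035, which became 0.0672 without HC T0 replicate 9). Camera called the NK list at an adjusted p of 2.46e-67, which held with an estimated correlation (adjusted p = 3.91e-05). The CD8 list had 3.44e-07 (adjusted p = 0.179 with an estimated correlation) and the non-classical monocyte list 1.85e-05 (adjusted p = 0.157 with an estimated correlation). None of 18 platelet genes was called by edgeR, also when adjusted over the list alone, though all were lower (median -0.47, camera 6.6e-05; adjusted p = 0.794 with an estimated correlation). Blocking by participant, as inferred from the deposited file names, raised the counts to 879 and 444. Leaving out HC T1 replicate 19 left 127 called genes, and with the marker means of 5 cell types as covariates, NK cells among them, edgeR called 0 (311 at an unadjusted p under 0.05).

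The change from rest to peak in GWI asks the same of the ill participants, and its main feature was a rise of NK transcripts. Of 22 NK markers, 13 rose, 21 when adjusted over the list alone, with a median log2 fold change of 0.87. S1PR5 rose from 45.9 ± 19.8 CPM at T0 (n = 20) to 86.8 ± 30.2 CPM at T1 (n = 18), GZMA from 71 ± 34 to 130 ± 44.5 CPM, and PTGDR (ENSG00000168229, chromosome 14, 52267713 to 52276724) from 30 ± 12.2 to 62.8 ± 34.2 CPM, each with an edgeR adjusted p of 0.0181. FASLG, the gene of the death receptor ligand of cytotoxic cells (ENSG00000117560, chromosome 1, 172659018 to 172666874), rose from 7.13 ± 3.3 to 16.1 ± 7.41 CPM, a log2 fold change of 1.17 (SE 0.214), and was higher in 15 of 16 participants. AKAP5, which encodes an anchoring protein of protein kinase A, rose from 7.55 ± 3.88 to 16.4 ± 6.66 CPM, in 16 of 16 participants. Of the 23 inflammatory cytokine and NF-kB target genes, IL1A (interleukin 1 alpha) and CCL20 (a chemokine) fell, by 4.46 (SE 0.924) and 3.64 (SE 0.833) on the log2 scale, and 10 fell when adjusted over the list alone.

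edgeR called 85 genes that rose and 3 that fell between T1 and T0 in GWI (DESeq2 132 and 7). The 5 highest were GFAP, SPARCL1, SNAP25, SLC1A2 and MAP2, genes of astrocytes and neurons, at log2 fold changes of 4.88, 4.79, 4.75, 4.09 and 3.15. They were high in a single library, GWI T1 replicate 9, without which GFAP had an adjusted p of 0.995, SPARCL1 0.962, SNAP25 0.955, SLC1A2 0.92 and MAP2 0.848. Without the 6 libraries that carry brain transcripts, 32 genes rose and 1 fell, and 8 of the 22 NK markers rose. Next came FASLG, AKR1C3, AKAP5, BNC2, PDGFRB, PTGDR and KLRF1, between 1.17 and 1.05. Without GWI T1 replicate 17 the adjusted p of AKR1C3, an aldo-keto reductase gene, became 0.0947, that of BNC2 0.0745, that of PDGFRB 0.09 and that of KLRF1 0.0811. Camera called the NK list at 1.51e-55, which held with an estimated correlation (adjusted p = 0.000617), and the cytokine list at 2.99e-05 (adjusted p = 0.85 with an estimated correlation). Without GWI T0 replicate 14, IL1A had an adjusted p of 0.0752 and CCL20 of 0.218. Blocking by inferred participant raised the counts to 1232 and 766, with 22 NK markers called. Single libraries moved the 88 calls between 26 and 178. Without GWI T0 replicates 3, 6, 9, 10, 11, 14 and 19 the counts were 58, 41, 52, 43, 56, 56 and 178. Without GWI T1 replicates 6, 7, 9, 12, 13 and 17 they were 140, 44, 33, 47, 153 and 26. With the 5 cell type covariates edgeR called 0 genes (903 at an unadjusted p under 0.05).

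**Figure D1:**
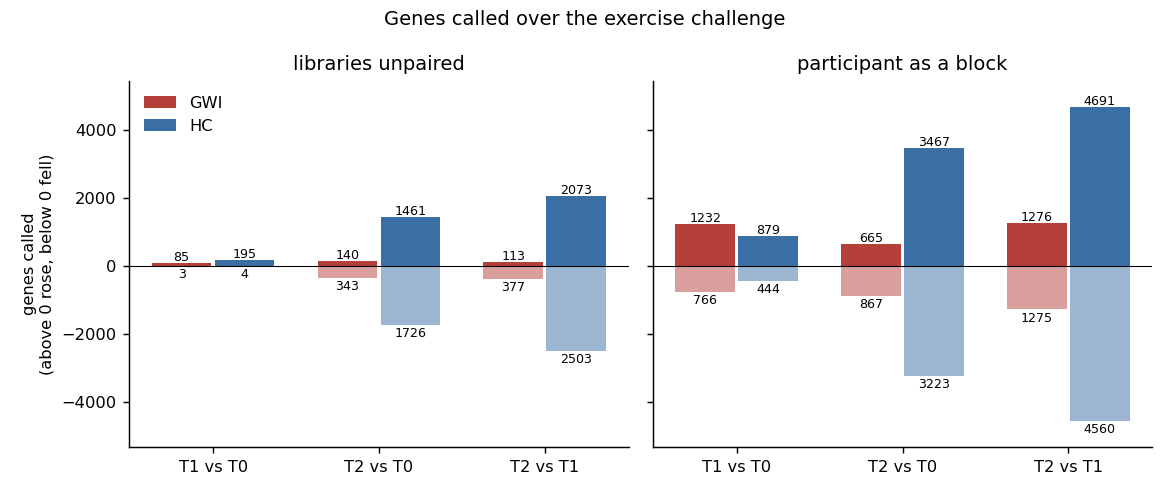
Number of genes called by edgeR in each comparison of times for GWI and HC, as bars above 0 for genes that rose and below 0 for genes that fell, with libraries unpaired on the left and the inferred participant as a block on the right. With libraries unpaired, HC had 3187 called genes between T2 and T0 and GWI 483.

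The change from rest to recovery in HC asks what persists 4 hours after the peak. Genes of the unfolded protein response, which is set off by misfolded protein in the endoplasmic reticulum, fell in 8 of 16 cases (8 when adjusted over the list alone, median -0.39). DDIT3, a transcription factor gene of that response (ENSG00000175197, chromosome 12, 57516588 to 57521737, where MIR616 lies within it), dropped from 67.6 ± 78.6 CPM at T0 (n = 19) to 13.7 ± 5 CPM at T2 (n = 20), a log2 fold change of -2.29 (SE 0.346, edgeR adjusted p = 4.76e-05). The chaperone gene HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) fell from 547 ± 525 to 146 ± 16.5 CPM. Of 24 immediate early genes, the first to respond to stimulation, 10 fell and 2 rose (15 and 2 when adjusted over the list alone, median -0.63). JUN, a subunit of the AP-1 transcription factor (ENSG00000177606, chromosome 1, 58780788 to 58784327), fell from 721 ± 850 to 155 ± 95.8 CPM, in 16 of 17 participants. Glucocorticoid-induced genes fell in 9 of 18 cases (11 when adjusted over the list alone, median -0.48), for instance TSC22D3, an anti-inflammatory regulator gene, from 825 ± 382 to 443 ± 96.9 CPM.

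Further lists fell in part between T0 and T2 in HC. Of 23 inflammatory cytokine and NF-kB target genes, 12 fell (15 when adjusted over the list alone, median -0.91), and TNFAIP3, an inhibitor of NF-kB, went from 1313 ± 932 to 376 ± 235 CPM. Of 18 histone genes 6 fell (6 when adjusted over the list alone), of 16 circadian clock genes 8 fell (8 when adjusted over the list alone), including PER2 (-0.90, SE 0.144) and CRY1 (-0.73, SE 0.143). Of 20 hypoxia and glycolysis genes 9 fell and 1 rose (11 and 1 when adjusted over the list alone), and ADM, the gene of the vasodilator adrenomedullin, fell by 1.69 (SE 0.237). Of 14 genes of adrenergic and steroid receptor signalling 6 fell (7 when adjusted over the list alone), with the phosphodiesterase gene PDE4D at -1.53 (SE 0.264). Of 19 oxidative stress (NRF2) genes 6 fell and 1 rose (8 and 1 when adjusted over the list alone), and the cystine transporter gene SLC7A11 fell by 2.16 (SE 0.367). Of 8 erythroid genes 4 fell (4 when adjusted over the list alone), HBB from 336 ± 564 to 46 ± 65.5 CPM. As given above, the T0 mean of HBB in HC rests on a few libraries. Of 17 heat shock genes 7 fell (10 when adjusted over the list alone), the chaperone gene DNAJB1 by 1.36 (SE 0.265). Among lymphocyte lists, 6 of 18 naive and central memory T cell genes rose (6 when adjusted over the list alone), among them CD40LG, CD27 and TCF7.

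Camera tests gave adjusted p values of 3.23e-07 for the unfolded protein response (adjusted p = 0.128 with an estimated correlation) and 4.07e-08 for immediate early genes (adjusted p = 0.23 with an estimated correlation). They gave 2.63e-07 for cytokines (adjusted p = 0.153 with an estimated correlation) and 9.08e-05 for histones (adjusted p = 0.595 with an estimated correlation). The clock genes had 1.34e-05 (adjusted p = 0.0624 with an estimated correlation) and the hypoxia genes 1.49e-05 (adjusted p = 0.128 with an estimated correlation). Camera gave 0.000991 for adrenergic signalling (adjusted p = 0.0624 with an estimated correlation) and 0.000102 for NRF2 genes (adjusted p = 0.153 with an estimated correlation). The erythroid list had 0.0388, the heat shock list 0.00524 and the naive T cell list 0.00524 (adjusted p = 0.648 with an estimated correlation in each of the 3). The glucocorticoid list had 2.63e-07 and held with an estimated correlation (adjusted p = 0.0135), though not with both that and the participant block (adjusted p = 0.0876). In all, edgeR called 1461 genes that rose and 1726 that fell between T0 and T2 in HC (DESeq2 1522 and 1858), and 3467 and 3223 with the block by inferred participant. The 12 highest included TMEM272, LRRN3, CD180, GIMAP7, GIMAP5, SIT1, ZNF594, CISH, CCR2, PAQR8 and CD200R1 (1.18 to 0.97), where GIMAP5 overlaps the read-through gene GIMAP1-GIMAP5. SIT1, a T cell receptor signalling adaptor gene (ENSG00000137078, chromosome 9, 35649295 to 35650950), rose from 11.6 ± 4.22 to 24 ± 9.52 CPM in 17 of 17 participants, and GIMAP7, a GTPase gene of lymphocytes, from 49 ± 20.9 to 104 ± 45.4 CPM. The 12 lowest were HBA2, HBB, SDC2, HSPA1B, NR4A3, HBA1, LAMB3, SEMA6B, DDIT3, G0S2, JUN and SLC7A5, between -3.03 and -2.16, of which HBA1 and HBA2 share nearly all of their sequence. HSPA1B, a heat shock protein 70 gene with a near copy in HSPA1A, rested on HC T0 replicate 16, without which its adjusted p was 0.111 (0.476 with the participant block).

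In GWI, the change from rest to recovery included falls of immediate early, cytokine and histone genes. JUN fell from 763 ± 1057 CPM at T0 (n = 20) to 96.3 ± 73.1 CPM at T2 (n = 20), a log2 fold change of -2.98 (SE 0.502, edgeR adjusted p = 0.000836), lower in 15 of 17 participants. In all 6 of 24 immediate early genes fell (17 fell and 1 rose when adjusted over the list alone, median -0.89), among them PPP1R15A, a gene of the stress response phosphatase, from 385 ± 388 to 119 ± 84.5 CPM. Of 23 cytokine and NF-kB genes 11 fell (15 when adjusted over the list alone, median -1.54), with IL1A at -4.81 (SE 0.873) and CCL20 at -4.02 (SE 0.788). Histone genes fell in 5 of 18 cases (8 when adjusted over the list alone, median -0.36), for instance HIST1H2BD (ENSG00000158373, chromosome 6, 26158146 to 26171349) from 146 ± 114 to 59.4 ± 22.8 CPM in 16 of 17 participants. Histone genes have near copies within their cluster, and reads that fit several genes equally were left out of the counts. Of 16 unfolded protein response genes 3 fell (4 when adjusted over the list alone, median -0.19), HSPA5 from 358 ± 357 to 142 ± 30.5 CPM and DDIT3 from 43.7 ± 51.1 to 14 ± 8.32 CPM.

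Smaller parts of other lists fell between T0 and T2 in GWI. Of 17 heat shock genes 4 fell (9 when adjusted over the list alone; camera adjusted p = 6.01e-05; adjusted p = 0.44 with an estimated correlation). Of 16 clock genes 2 fell (4 fell and 1 rose when adjusted over the list alone; camera 0.00278; adjusted p = 0.243 with an estimated correlation), and of 20 hypoxia genes 1 fell (5 when adjusted over the list alone; camera 8.14e-05; adjusted p = 0.243 with an estimated correlation). PER2 fell from 34 ± 12.3 to 23.8 ± 4.43 CPM and ADM from 9.72 ± 10.4 to 3.27 ± 2.32 CPM. None of the 18 glucocorticoid-induced genes was called by edgeR (4 fell when adjusted over the list alone; camera 3e-05; adjusted p = 0.243 with an estimated correlation). The smallest p in that list was that of PER1, at 0.00141 unadjusted, with 231 ± 178 CPM at T0 and 110 ± 71.5 CPM at T2 (adjusted p = 0.0546). Camera gave 2.44e-16 for immediate early genes, 2.79e-08 for cytokines, 2.91e-09 for histones and 1.79e-05 for the unfolded protein response (adjusted p = 0.243 with an estimated correlation in each of the 4).

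edgeR called 140 genes that rose and 343 that fell between T0 and T2 in GWI (DESeq2 58 and 450), and 665 and 867 with the participant block. The 12 highest, SPARCL1, GFAP, SNAP25, KIF1A, NTRK2, SLC1A2, NDRG4, ATRNL1, MAP2, ANK2, SYT1 and MAP1B, with log2 fold changes of 6.03 to 4.10, are genes of nerve cells and glia. All 12 rested on GWI T2 replicate 2, without which their adjusted p lay between 0.569 and 0.994. Without the 6 libraries that hold brain transcripts 9 genes rose and 157 fell. These 12 genes then had log2 fold changes below 0, with SPARCL1 (-2.83, adjusted p = 0.0348), GFAP (-2.12, 0.0326) and SLC1A2 (-1.83, 0.0348) called lower. In this comparison that choice took libraries from T2 only, replicates 2 and 10, for their high brain markers. These p values thus do not test a fall, and GFAP reached at most 4.29 CPM in the libraries that remained. The 12 lowest were AL031777.3, TEX14, JUN, HSPA1B, IL1B, CSKMT, IFNG, TNF, HIST1H2BB, EREG, CXCL2 and SERPINB2, between -3.34 and -2.20. AL031777.3 overlaps 2 histone genes, TEX14 holds copies of the small nuclear RNA gene RNU1 and CSKMT holds SNORA57, so part of their counts can come from those. Without GWI T0 replicate 14 the adjusted p was 0.0909 for IL1B, 0.129 for EREG and 0.151 for CXCL2, and without GWI T0 replicate 19 it was 0.146 for HSPA1B and 0.208 for IFNG. With the participant block these 5 were not called (adjusted p = 0.104, 0.0842, 0.0748, 0.66 and 0.149), nor was TNF (0.191). The 483 calls became 294, 321, 751 and 315 without GWI T0 replicates 11, 14, 15 and 19, and 245 without GWI T2 replicate 2.

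**Figure D2:**
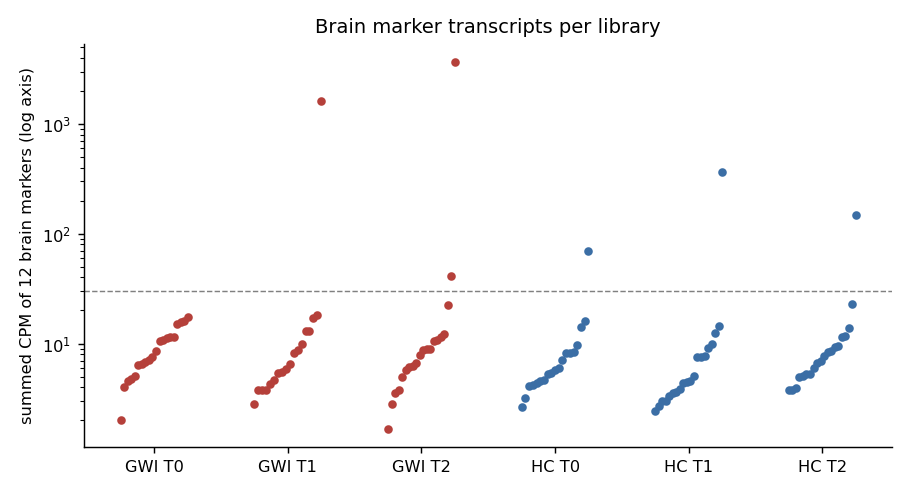
Summed CPM of 12 brain marker genes in each of the 117 libraries, by group, on a log axis with a dashed line at 30 CPM. The 6 libraries above the line include GWI T2 replicate 2 at 3642 CPM and GWI T1 replicate 9 at 1611 CPM, while the highest of the others had 22.7 CPM.

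From the peak of exercise to recovery, NK markers fell in HC in 20 of 22 cases (22 when adjusted over the list alone, median -1.31). GZMB fell from 192 ± 65.9 CPM at T1 (n = 20) to 57.4 ± 22.8 CPM at T2 (n = 20), a log2 fold change of -1.75 (SE 0.17, edgeR adjusted p = 6.36e-09), in 19 of 19 participants. It ended below its resting level (T2 against T0 -0.56, SE 0.166, adjusted p = 0.0183). FGFBP2, a gene expressed by cytotoxic lymphocytes, fell from 146 ± 50.5 to 50 ± 18.2 CPM. B3GNT7, a glycosyltransferase gene (ENSG00000156966, chromosome 2, 231395543 to 231401164), fell from 47.2 ± 32.3 to 8.56 ± 5.41 CPM. Naive and central memory T cell genes rose in 11 of 18 cases (14 when adjusted over the list alone, median 0.56; camera adjusted p = 0.193 with an estimated correlation). TCF7, a transcription factor gene of naive T cells (ENSG00000081059, chromosome 5, 134114711 to 134151865), rose from 249 ± 81.8 to 439 ± 132 CPM in 19 of 19 participants. B cell genes rose in 8 of 17 cases (14 when adjusted over the list alone, median 0.56; camera adjusted p = 0.462 with an estimated correlation), for instance FCRL2 from 18.4 ± 9.01 to 32.3 ± 14 CPM. MYC, a growth-promoting transcription factor gene (ENSG00000136997, chromosome 8, 127735434 to 127741434), rose from 40.1 ± 13.1 to 78.7 ± 30.2 CPM.

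Stress genes also fell between T1 and T2 in HC. Of 16 unfolded protein response genes 10 fell (14 when adjusted over the list alone, median -0.47), with HSPA5 at -1.69 (SE 0.255) and HYOU1 lower in 19 of 19 participants. Of 17 heat shock genes 11 fell (13 when adjusted over the list alone, median -0.80), DNAJB1 by 1.64 (SE 0.34). Of 23 cytokine and NF-kB genes 9 fell (9 when adjusted over the list alone), the chemokine gene CCL4 from 72.5 ± 33.3 to 21.4 ± 15.1 CPM in 19 of 19 participants. Of the 12 genes listed as non-classical monocyte markers 4 fell (4 when adjusted over the list alone), the Fc receptor gene FCGR3A from 375 ± 145 to 186 ± 76.7 CPM. Counts of mixed cells do not tell which cell type the fall of FCGR3A came from. Of 12 CD8 T cell genes 4 fell (4 when adjusted over the list alone), the granzyme gene GZMH by 1.32 (SE 0.232). Of 18 histone genes 4 fell (4 when adjusted over the list alone, median -0.32), and of 24 immediate early genes 10 fell and MYC rose (11 fell and 2 rose when adjusted over the list alone). Of 77 nuclear oxidative phosphorylation genes 11 fell (7 when adjusted over the list alone, median -0.18), the cytochrome c gene CYCS by 0.61 (SE 0.135).

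The NK list was called by camera at 4.43e-39 and held with an estimated correlation (adjusted p = 0.00192). The naive T cell list had 3.11e-08 (adjusted p = 0.193 with an estimated correlation, 0.0274 with that and the participant block), the B cell list 1.48e-05 (adjusted p = 0.462 with an estimated correlation) and the unfolded protein response 8.74e-09 (adjusted p = 0.0741 with an estimated correlation). The lists of non-classical monocytes (camera 0.000543; adjusted p = 0.235 with an estimated correlation), heat shock (0.00119), cytokines (0.00172), histones (0.000988), oxidative phosphorylation (1.52e-05) and CD8 T cells (0.0302) followed, the last 5 with adjusted p = 0.541 with an estimated correlation, and immediate early genes had 0.00259 (adjusted p = 0.582 with an estimated correlation). Between T1 and T2 in HC, edgeR called 2073 genes that rose and 2503 that fell (DESeq2 2098 and 2635), and 4691 and 4560 with the participant block. With the 5 cell type covariates 872 rose and 1359 fell. The 12 highest included TMEM272, LRRN3, CD180, NOG, TCL1A, CCR2, GIMAP5, EPHA1, BTLA, MYC and TTC34 (1.74 to 0.95), and the 12 lowest HSPA1B, B3GNT7, JUN, IFNG, NR4A3, HBA2, DDIT3, AKAP5, HSPA6, MAFF, HSPA1A and KIR3DL1 (-3.71 to -1.80). IFNG, the gene of interferon gamma, fell from 11.6 ± 17.6 to 2.26 ± 1.35 CPM. Without HC T1 replicate 17 the adjusted p was 0.0726 for HSPA1B, 0.109 for HSPA6 and 0.492 for HSPA1A, and with the participant block it was 0.484, 0.467 and 0.651. HBA2 had 0.0893 without HC T1 replicate 5 (0.232 with the block), and KIR3DL1, a killer cell receptor gene with close paralogs, was lower in 19 of 19 participants.

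In GWI from T1 to T2, NK transcripts fell as well, in 20 of 22 cases (21 when adjusted over the list alone, median -0.99). PRF1 went from 878 ± 390 CPM at T1 (n = 18) to 424 ± 140 CPM at T2 (n = 20), a log2 fold change of -1.05 (SE 0.177, edgeR adjusted p = 0.000739), lower in 17 of 17 participants, and GZMB from 159 ± 71.3 to 66.7 ± 32.6 CPM. Of 18 naive and central memory T cell genes 3 rose (12 when adjusted over the list alone, median 0.48). TCF7 rose from 270 ± 93 to 392 ± 100 CPM, the costimulatory receptor gene CD27 from 21.7 ± 9.78 to 33.9 ± 11.5 CPM, and the CD40 ligand gene CD40LG from 12.6 ± 2.99 to 17.6 ± 5.62 CPM. MYC rose from 49 ± 16.8 to 79.8 ± 24.5 CPM in 16 of 17 participants, as the 1 immediate early gene to rise beside JUN, the 1 to fall (1 and 4 when adjusted over the list alone). Histone genes fell in 5 of 18 cases (9 when adjusted over the list alone, median -0.35), HIST1H2BD from 146 ± 97.9 to 59.4 ± 22.8 CPM. Of 16 unfolded protein response genes 3 fell (7 when adjusted over the list alone, median -0.26), HSPA5 from 289 ± 239 to 142 ± 30.5 CPM. Of the 12 genes listed as non-classical monocyte markers FCGR3A fell, from 378 ± 130 to 226 ± 70.7 CPM (2 when adjusted over the list alone). Since NK markers fell over the same interval, counts of mixed cells do not tell which cell type the fall of FCGR3A came from.

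Camera called the NK list at 2.66e-43, which held with an estimated correlation (adjusted p = 0.00252). The naive T cell list had 1.4e-12 (adjusted p = 0.19 with an estimated correlation, 0.00149 with that and the participant block) and the histone list 6.73e-11 (adjusted p = 0.256 with an estimated correlation). The unfolded protein response had 3.31e-08 (adjusted p = 0.203 with an estimated correlation) and immediate early genes 0.000995 (adjusted p = 0.573 with an estimated correlation). Non-classical monocytes had 0.0045 (adjusted p = 0.459 with an estimated correlation). edgeR called 113 genes that rose and 377 that fell between T1 and T2 in GWI (DESeq2 177 and 540), 1276 and 1275 with the participant block, and 0 and 2 with the 5 cell type covariates (2501 at an unadjusted p under 0.05). The 12 highest were PDK4, MYC, GIMAP5, CACNA1I, VSIG1, CD27, EPHA1, EPHB6, GNG7, SUSD3, SYDE2 and STMN3 (0.80 to 0.56), and the 12 lowest AL031777.3, IFNG, JUN, HSPA1B, HIST1H2BB, CSKMT, HIST1H2AB, HIST1H2BG, HIST1H2AH, HIST2H2BF, HIST1H3J and KIR3DL1 (-3.06 to -1.43). Without GWI T1 replicate 15 the adjusted p was 0.0508 for CD27, 0.173 for HSPA1B and 0.0761 for HIST1H3J. It was 0.0578 for GIMAP5 without GWI T2 replicate 10, 0.0545 for SYDE2 without GWI T1 replicate 17, 0.0865 for KIR3DL1 without GWI T1 replicate 7 and 0.0841 for CD40LG without GWI T2 replicate 11. With the participant block JUN (adjusted p = 0.0548) and HSPA1B (0.289) were not called. Leaving out GWI T1 replicate 9 raised the 490 calls to 770.

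**Figure D3:**
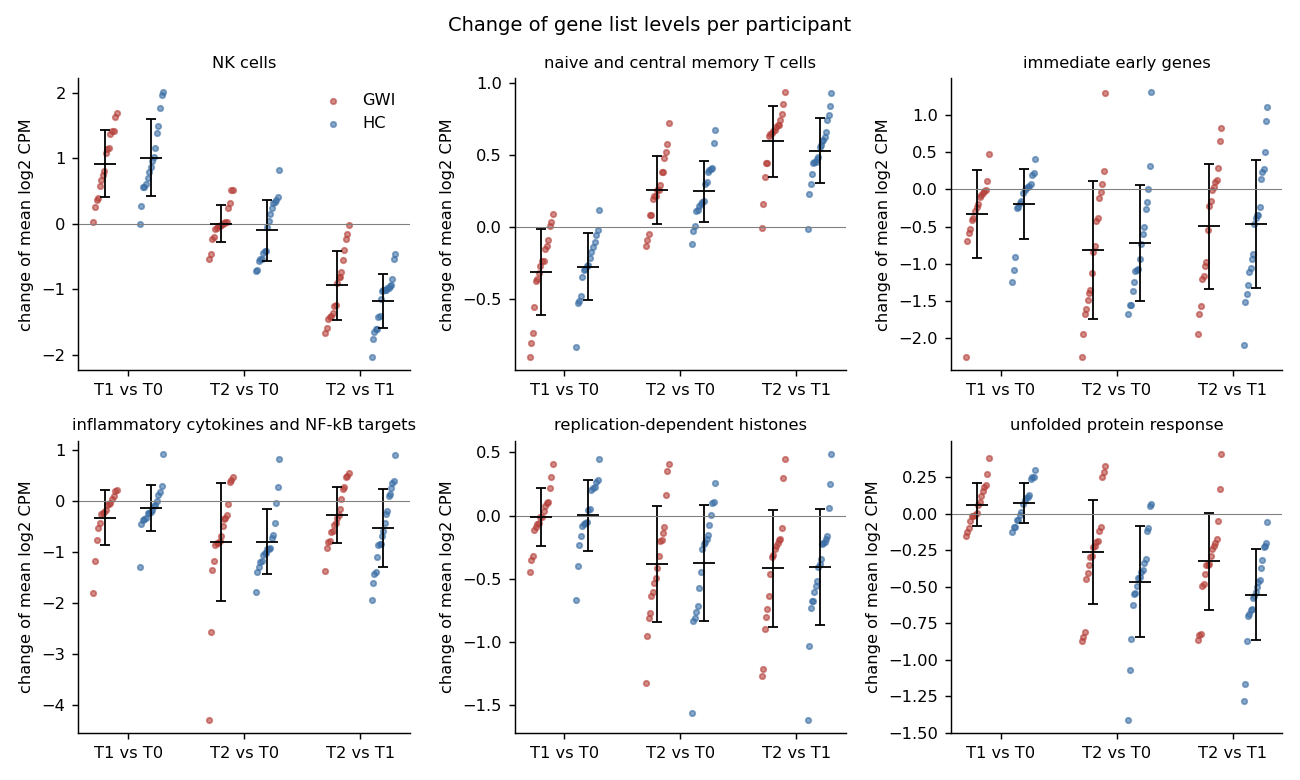
Change of the mean log2 CPM of 6 gene lists between the times, with a point per inferred participant and bars for the mean and SD of GWI and HC. The mean of the NK list is above 0 for T1 against T0 and below 0 for T2 against T1, at -0.94 in GWI and -1.18 in HC.

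Whether the change over the exercise challenge differs with the illness was tested as an interaction, the change in GWI minus the change in HC. The gene of smallest p from T0 to T2 was SLCO4A1, whose log2 fold change was -0.10 in GWI (n = 20 and 20) and -2.14 in HC (n = 19 and 20), a difference of 2.05 (SE 0.482, edgeR adjusted p = 0.334). SLC7A11 followed, with 0.15 in GWI and -2.16 in HC, a difference of 2.32 (SE 0.553). SMARCE1P6 (-1.28), AC019186.1 (-1.34) and RNA5SP344 (-1.25) had the same adjusted p of 0.334. From T0 to T1 the smallest p belonged to GALNT14 (1.10, SE 0.288), IL1A (-3.59, SE 1.11), MIR155HG (-1.87), MS4A3 (1.59) and DEFA3 (2.60), all with an edgeR adjusted p of 1. From T1 to T2 it belonged to AC019186.1 (-1.15), SLCO4A1 (1.86), BEND3 (0.58), PPP1R16B (0.61) and TNFRSF21 (1.16), with the same adjusted p of 1.

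edgeR called 0 genes in each of the 3 interactions, with 117, 1141 and 722 genes at an unadjusted p under 0.05 for T1 against T0, T2 against T0 and T2 against T1, and DESeq2 called 0. With the participant block 1 gene was called for T2 against T0, and leaving out GWI T0 replicate 12 gave 3 there. None of the differences in called genes between GWI and HC described above for NK, T cell, stress or cytokine genes passed this test for a single gene. Camera called 7, 9 and 12 of the 29 lists in the 3 interactions, of which 0 held with an estimated correlation (lowest adjusted p = 0.913, 0.559 and 0.503). With the participant block camera called 1, 8 and 7 lists in turn. The cholinergic and esterase list, chosen because pesticides and nerve agents that inhibit cholinesterases are among the exposures studied in GWI, had medians of 0.01, 0.03 and 0.01 in the interactions and of 0.02, 0.08 and 0.10 between GWI and HC at T0, T1 and T2. Its camera adjusted p lay between 0.538 and 0.964 in these 6 comparisons, with adjusted p values between 0.794 and 0.989 with an estimated correlation, and 0 of 8 members were called by edgeR (1 higher at T2 when adjusted over the list alone).

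Across the 20607 tested genes the changes between times in GWI went along with those in HC. The log2 fold changes of the conditions correlated with Pearson r 0.656 and Spearman rho 0.696 from T0 to T1, 0.557 and 0.638 from T0 to T2, and 0.682 and 0.733 from T1 to T2. These are correlations across genes, and genes are not independent replicates. From T0 to T1, 62 genes rose in both conditions where 0.804 would be met by chance if genes were independent. Genes vary together, so this and the following chance values do not measure how unlikely the overlaps are. From T0 to T2, 33 rose and 264 fell in both (9.93 and 28.7 by chance), and from T1 to T2 95 rose and 341 fell in both (11.4 and 45.8 by chance). Without the 6 libraries that hold brain transcripts 25 genes rose in both from T0 to T1 (0.216 by chance), and from T0 to T2 3 rose and 128 fell in both (0.608 and 12.8 by chance). With libraries unpaired, 0 genes called in both conditions moved in opposite directions. Blocked by participant, 0 did from T0 to T1, 2 from T0 to T2 and 1 from T1 to T2. The slopes of the GWI changes on those in HC were 0.752, 0.608 and 0.544. Noise in the HC changes lowers such slopes, so they do not show a smaller response in GWI. The SD of the changes across genes was 0.309, 0.437 and 0.334 in GWI and 0.270, 0.401 and 0.419 in HC. Without the 6 libraries it was 0.268, 0.335 and 0.316 in GWI and 0.269, 0.417 and 0.429 in HC.

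**Figure D4:**
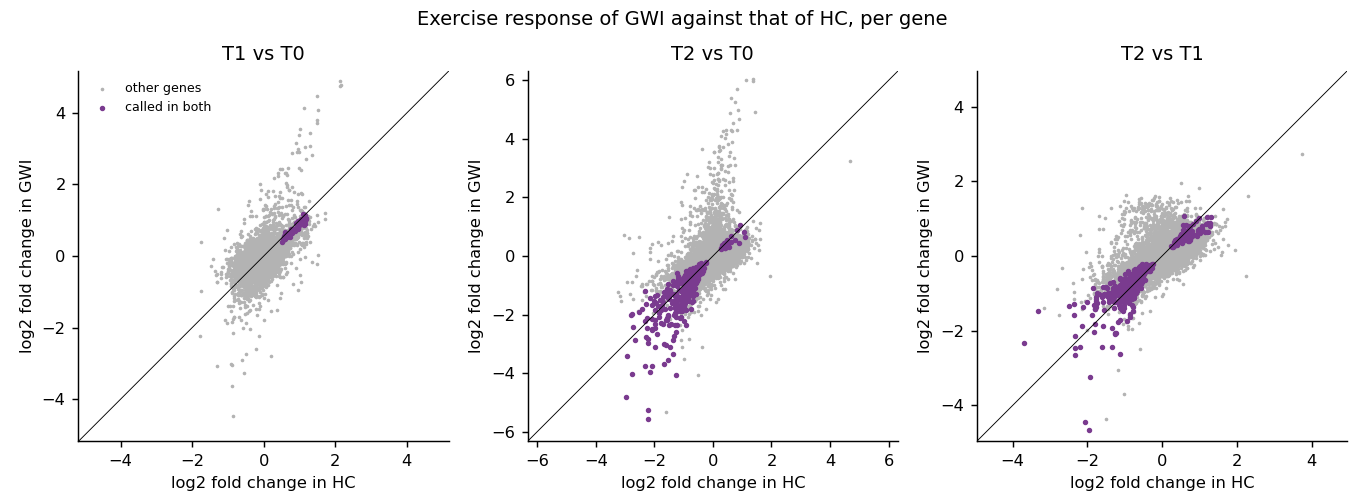
Log2 fold change in GWI against that in HC for each tested gene in the 3 comparisons of times, with the genes called in both conditions marked. The called genes lie in the quadrants of like sign, and Pearson r is 0.656 from T0 to T1, 0.557 from T0 to T2 and 0.682 from T1 to T2.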

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

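The tests of the brain transcripts, of the members that stay called, without the 6 libraries, with the GC offset, of spread and shared response, of permuted list means, of p values over the splits and of splits with the participant block were chosen only after the results were seen, whereas the other splits of the samples, both camera correlations, the participant block and the covariates were fixed before the data were examined. The transcripts of brain genes in 6 libraries stand out as samples far from the others: 12 brain marker genes summed to 3642 CPM in GWI T2 replicate 2, 1611 in GWI T1 replicate 9, 365 in HC T1 replicate 14, 150 in HC T2 replicate 12, 69.5 in HC T0 replicate 2 and 40.9 in GWI T2 replicate 10, against a median of 6.55 in the other libraries. GWI alone does not account for these transcripts, since 3 of the 6 libraries are HC. The highest values, in GWI T2 replicate 2 and GWI T1 replicate 9, are both of GWI. With 6 libraries an effect of GWI on the amount cannot be judged. A lasting state of the participants stays open. The 9 other libraries of those participants had 7.54 to 18.3 CPM, above that median. They were under the 30 CPM cut by definition, so their highest value cannot decide the question. Among the 6 libraries, GWI T1 replicate 9 and GWI T2 replicate 10 share an inferred participant. Brain RNA mixed into single libraries may explain the values, because the markers keep like ratios in the 3 libraries with most of them (lowest pairwise r 0.996), but brain tissue of any source would share such ratios, so the origin stays open. The connective tissue gene DCN reached 23.9 CPM in the 6 libraries and at most 0.771 CPM elsewhere.

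Lower immediate early, cytokine, histone and unfolded protein response genes at T2 than at T0 were seen in both conditions, with 36 of 81 measured members called lower in HC and 25 in GWI. In HC 36 of these stay called with an offset for GC content, 36 with the cell type covariates and 34 with depth and reads outside genes as covariates. A bias of GC content, of the measured cell makeup or of depth is therefore unlikely to be the whole cause in HC. The 25 genes called in GWI had a median log2 fold change of -1.75 (median SE 0.43). With the GC offset 25 stay called (median -1.69, SE 0.408), with the cell type covariates 16 (-1.35, SE 0.397) and with depth and reads outside genes 18 (-1.81, SE 0.456). Blocking by participant kept 17 called (-0.99, SE 0.309), and 14 stay called without the 6 libraries (-1.69, SE 0.45). With depth and reads outside genes, and without the 6 libraries, the median hardly moved and the SE was larger, so these lost calls do not count for depth as the cause. With the cell type covariates the median itself shrank, and a share of the cell makeup in the GWI values stays open. The median shrank further with the participant block, which used fewer libraries and does not measure cell makeup. The time between blood draw and separation of the cells, the hour of the day and the exercise itself could each alter such genes, and the files do not part them.

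Fewer genes were called between T2 and T0 in GWI (483) than in HC (3187). Brain transcripts in GWI libraries are unlikely as the cause, since without the 6 libraries the ratio of HC to GWI calls was 18.5 (6.60 with all libraries). Blocked by participant the ratio was 4.37, and the calls with that block and without the 6 libraries were 6014 in HC and 969 in GWI. A larger spread of the changes within participants in GWI could not be shown or excluded (permutation p = 0.663, ratio of mean squared deviations 0.891). The 483 and 3187 calls came from libraries unpaired, where the spread between libraries of a group counts. That spread was not compared between GWI and HC, so it stays open as a cause. A smaller shared response in GWI is a candidate explanation that the test could not tell either: the projection of each participant's change on the shared change was 0.702 ± 0.640 (n = 17) in GWI and 1.12 ± 0.682 (n = 17) in HC, permutation p = 0.0759. From T1 to T2 the same measure had p = 0.0283 (adjusted p = 0.0848 over the 3 contrasts).

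Gene lists were also singled out where their change differed between GWI and HC by camera with its preset correlation, with and without the participant block. From T0 to T2 the median differences on the log2 scale were 1.64 for erythroid cells, 0.128 for glucocorticoid-induced genes, 0.116 for oxidative phosphorylation, 0.214 for ribosomal proteins, 0.16 for the unfolded protein response, 0.286 for clock genes and 0.0836 for adrenergic and steroid receptor signalling. Their camera adjusted p values were 0.0069, 0.0295, 1.02e-06, 6.25e-12, 0.00327, 0.00124 and 0.0357, and with an estimated correlation the adjusted p values were 0.771, 0.771, 0.78, 0.78, 0.771, 0.559 and 0.559. From T1 to T2 the differences were 0.287 for NK cells, -0.264 for classical monocytes, 0.0977 for oxidative phosphorylation, 0.145 for ribosomal proteins, 0.144 for the unfolded protein response, 0.353 for clock genes and 0.171 for cell cycle genes. Their camera adjusted p values were 6.04e-05, 0.003, 2.51e-05, 5.11e-07, 0.000798, 0.000198 and 0.00118, and with an estimated correlation 0.672, 0.672, 0.672, 0.708, 0.672, 0.503 and 0.672. Blocking by participant moved some of these medians by over 1.5 times, to 0.224 for glucocorticoid-induced genes from T0 to T2, and from T1 to T2 to 0.258 for ribosomal proteins. Permutation of participants gave a lowest adjusted p of 0.46 from T0 to T2 and of 0.152, for ribosomal proteins, from T1 to T2.

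NK genes fell by a mean of -0.94 ± 0.53 log2 units per participant in GWI (n = 17) and -1.18 ± 0.42 in HC (n = 19) from T1 to T2. Clock genes had mean changes of -0.12 ± 0.32 in GWI (permutation p = 0.142 for the change within GWI) and -0.36 ± 0.25 in HC. Permutation of the difference between the conditions gave p = 0.0175 for clock genes (adjusted p = 0.169). Ribosomal protein genes had mean changes of 0.11 ± 0.31 in GWI and -0.13 ± 0.20 in HC over the same interval. From T0 to T2 erythroid genes had mean changes of -0.10 ± 0.81 in GWI and -0.79 ± 1.24 in HC (n = 17 in each).

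Regrouping the libraries at random shows whether chance can be excluded where genes were called. For GWI against HC at T2, 69 of 100 splits reached the 1 real gene (highest other split 766), so chance cannot be excluded there. Where 0 genes were called any split reaches the real count, and that count says nothing about chance: 100 of 100 splits for GWI against HC at T0 (highest other 319) and 100 at T1 (highest 2542), and 100 in each of the 3 interactions (highest others 16, 32 and 185). Counts of genes with an unadjusted p under 0.05 can tell more. The 1995 such genes at T0 were reached by 16 of 100 splits and the 1988 at T1 by 19. For the interactions of T1 against T0, T2 against T0 and T2 against T1, the 117, 1141 and 722 such genes were reached by 97, 13 and 28 of 100 splits. By this count, with libraries unpaired, chance cannot be excluded in any of the 5. Exchanging participants between the conditions in the blocked fit, the 583, 2295 and 3015 such genes of the interactions were reached by 87, 8 and 3 of 100 splits. The 1 gene called for T2 against T0 in that fit was reached by 21 of 100 (highest other 18). The 3 of 100 for T2 against T1 was the lowest of 3 counts and was not adjusted over them. It came from splits added after the data were seen, and 28 of 100 reached the unpaired count. Chance is thus not excluded for T2 against T1 either. Between times, the real count was reached by 1 of 100 splits for T1 against T0 in GWI (88 genes, highest other 59), 2 for T2 against T0 in GWI (483, highest 3063), 3 for T2 against T1 in GWI (490, highest 6610), 4 for T1 against T0 in HC (199, highest 4860), 2 for T2 against T0 in HC (3187, highest 4529) and 1 for T2 against T1 in HC (4576, highest 1663). Splits that call several times the real count, as with 4860 against 199, point to a structure of the samples, and what such splits share was not tested. In further splits libraries were exchanged within participants, and libraries without a partner were shuffled among themselves. There 1 of 100 splits, the real one, reached the real count in each of the 6 comparisons. The highest others in GWI were 7, 143 and 140 for T1 against T0, T2 against T0 and T2 against T1. In HC they were 2, 10 and 8.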

How the results depend on the processing

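Tests chosen only after the results were seen were those without the 6 libraries that hold brain transcripts, with the GC offset, without each library in turn and with permutation of list means. Of 152 pairs of named gene and comparison, in which a gene can recur, 152 kept direction and side of the threshold with RLE normalization. With the GC offset 152 did, 146 with the library number series, 132 without a filter and 126 without the 6 libraries. With DESeq2 123 did, 121 with technical covariates, 109 with the title number as a block and 79 with cell makeup covariates. With the participant block 108 of 137 did, and 105 with that block and without the 6 libraries. Without each library in turn the called genes ranged from 0 to 3 for GWI against HC at T0, 0 to 3 at T1 and 1 to 48 at T2. In GWI they ranged from 26 to 178 for T1 against T0, 245 to 751 for T2 against T0 and 345 to 770 for T2 against T1. In HC the ranges were 127 to 294, 2547 to 4058 and 3915 to 5977, and in the interactions 0 to 0, 0 to 3 and 0 to 0. The lowest library has 7.85 M reads in genes, and genes of a few CPM rest on few reads there.

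Counts of called genes moved by more than 1.5 times under these alternatives, and the cause was not tested unless given. With the participant block they were 1998 for T1 against T0, 1532 for T2 against T0 and 2551 for T2 against T1 in GWI, 1323, 6690 and 9251 in HC, and 1 for the T2 against T0 interaction. With that block and without the 6 libraries they were 1739, 969 and 2105 in GWI and 970, 6014 and 8710 in HC. Without the 6 libraries alone they were 33 for T1 against T0 and 166 for T2 against T0 in GWI. Fewer libraries were tested there and the named brain genes were no longer called higher. SPARCL1, GFAP and SLC1A2 were called lower at T2, where libraries had been left out for their high brain markers. The correlation of the responses from T0 to T2 became 0.679. Without a filter the counts were 666 for GWI against HC at T0 and 480 at T2. They were 248 for T1 against T0 and 1060 for T2 against T0 in GWI, and 1 for the T2 against T0 interaction. At T0 that fit had 44176 genes and an infinite prior df in place of a median of 5.41, which shrank the SE of HBB from 0.773 to 0.121.

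DESeq2 called 1 gene for GWI against HC at T0, 11 at T1 and 139 for T1 against T0 in GWI. The title number as a block gave 2 at T0 for GWI against HC, 950 for T1 against T0 and 84 for T2 against T0 in GWI, and 9214 for T2 against T1 in HC. Cell makeup covariates gave 2 for GWI against HC at T0, 0, 1345 and 2 in GWI and 0, 4893 and 2231 in HC for T1 against T0, T2 against T0 and T2 against T1. The NK list is itself one of these covariates, so by construction they remove what follows NK cells. The library number series gave 151 for T1 against T0 in GWI. The GC offset gave 145 for T1 against T0 and 745 for T2 against T0 in GWI, and 327 and 4833 in HC. With the genes of the series table alone 0 were called for GWI against HC at T2, since that table lacks MIR3143, and 218 for T2 against T0 in GWI. Camera called 154 of 348 pairs of list and comparison, 5 with an estimated correlation, and 161 and 5 in turn without the 6 libraries. In the 261 pairs that the participant block covers it called 118 without the block, 121 with it and 6 with an estimated correlation as well, and 120 and 6 without the 6 libraries. Permutation called 72 of the 348, which need not be among the 154, since from T1 to T2 in HC it called 23 lists and camera 18. In GWI permutation called 5, 11 and 11 of 29 lists for T1 against T0, T2 against T0 and T2 against T1. In HC it called 8, 14 and 23. Permutation asks whether the mean of a list changed, while camera compares the list with the other genes.

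Without the 6 libraries the brain genes named in GWI lost their rise by construction, since those libraries held them. The values below 0 do not follow from that alone, and the cause was not tested. The libraries left out in GWI, T1 replicate 9 and T2 replicates 2 and 10, were chosen for high brain markers. Values and p values of brain genes in the rest thus do not test a fall from T0. From T0 to T1, without the 6 libraries GFAP had -0.023, SLC1A2 -0.25 and MAP2 -0.25, and with the participant block as well -0.048, -0.14 and -0.23, while SPARCL1 (0.16) and SNAP25 (0.18) did not reverse without the 6 libraries. With DESeq2 GFAP had -0.28, SPARCL1 -0.14, SNAP25 -0.087, SLC1A2 -0.45 and MAP2 -0.31, for which the cause was not tested. From T0 to T2, without the 6 libraries, SPARCL1 had -2.83, GFAP -2.12, SNAP25 -1.33, KIF1A -0.76, NTRK2 -0.68, SLC1A2 -1.83, NDRG4 -0.36, ATRNL1 -0.56, MAP2 -0.24, ANK2 -1.02, SYT1 -0.42 and MAP1B -0.56. With the participant block as well they had -2.38, -1.66, -0.72, -0.37, -0.53, -1.57, -0.20, -0.61, -0.18, -0.68, -0.31 and -0.43. Of these, SPARCL1, GFAP and SLC1A2 were called lower at T2 without the 6 libraries (adjusted p = 0.0348, 0.0326 and 0.0348), and with the block as well (adjusted p = 0.0338, 0.0243 and 0.0326). With DESeq2 SPARCL1 had -0.51, GFAP -0.38, SNAP25 -0.33, KIF1A -0.084, NTRK2 -0.33, SLC1A2 -0.57, ATRNL1 -0.26, MAP2 -0.070, ANK2 -0.25, SYT1 -0.20 and MAP1B -0.36. With the title number as a block GFAP had -0.10 and SLC1A2 -0.24, and the cause was not tested.

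With cell makeup covariates KIR3DL1 from T1 to T2 reversed to 0.17 in GWI and 0.24 in HC, and from T0 to T1 in HC ADAMTS1 to -0.043, KLRF1 to -0.16, PTGDR to -0.36, ENPP5 to -0.25, CXCR1 to -0.32 and SLC25A37 to 0.045. KLRF1 and PTGDR are members of the NK list, whose mean is one of these covariates, so they lose their rise by construction. For the other genes, and for the signs of the reversed values, the cause was not tested. From T1 to T2 in HC HSPA6 reversed to 0.38 with the participant block, 0.43 with that and without the 6 libraries, 0.48 with DESeq2 and 0.36 with the title number as a block, and HSPA1A to 0.25, 0.44, 0.22 and 0.23. The cause was not tested. The ribosomal protein list in the interaction of T1 against T0 reversed from 0.06 to -0.01 with the participant block and without the 6 libraries (-0.0136) and in the permutation of list means (-0.00936), and the cause was not tested.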

Other observations

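All tests of these gene families were chosen only after the results were seen. The GIMAP genes, which encode GTPases of lymphocytes and lie side by side on chromosome 7, rose from T0 to T2 in 7 of 7 measured cases in HC, with log2 fold changes between 0.43 and 1.09 (median 0.96). In GWI 3 of 7 rose, GIMAP5 by 0.81 (SE 0.204, edgeR adjusted p = 0.0227), GIMAP7 by 0.63 (adjusted p = 0.0286) and GIMAP6 by 0.45 (adjusted p = 0.0407), with a median over the family of 0.41 and 6 called with the participant block. The interaction called 0 of the 7, with a median of -0.43. From T1 to T2 5 rose in HC (median 0.51) and 1 in GWI (median 0.21).

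The killer cell immunoglobulin-like receptor genes, which encode inhibitory and activating receptors of NK cells, fell from T1 to T2 in 5 of 5 measured cases in GWI (median -1.43) and in HC (median -1.88). The log2 fold change of KIR2DL1 was -1.88 (SE 0.301, edgeR adjusted p = 0.000397) in GWI and -2.14 (SE 0.322, adjusted p = 8.75e-06) in HC. From T0 to T1 KIR2DL1 alone rose in GWI (1.38, SE 0.301, adjusted p = 0.0244), 0 of 5 in HC, and 5 in each condition with the participant block. The interactions called 0 of the 5. These genes share much of their sequence and differ in number between people, so the counts of a single member are uncertain.

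Of 4 metallothionein genes, which bind metal ions, 1 fell from T0 to T2 in GWI (family median -1.03), where the participant block called 0 and gave a median of -0.28. In HC that block called 1 lower over the same interval (0 without it). From T0 to T1 the GWI median was -1.05, and 0.046 with the block, with 0 called in either. From T1 to T2 1 fell in HC (median -0.14, and -0.090 with the block). Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs, 1 rose and 3 fell from T0 to T2 in HC and 4 fell from T1 to T2, with 0 called in GWI in these 2 contrasts. The participant block gave 3 that rose and 3 that fell from T0 to T2 in HC and 1 and 8 from T1 to T2, and in GWI 1 and 2 that fell. The interactions called 0 members of either family.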
